A study of Mus musculus with 4 samples.

How the data were processed

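The series holds 4 mouse libraries from bone marrow cells of the lin- c-Kit+ fraction, called LIC in the labels. RNA bound by IGF2BP2, YTHDF2 or YTHDC1 was immunoprecipitated in 1 library each, and 1 library is the input. Per the labels' protocols, cells were crosslinked with UV light of 254 nm (120 mJ per cm2, 3 exposures) and sonicated. Stranded libraries were then amplified for 20 cycles and selected at 250 to 450 bp. Each protein has a single library, so no difference between readers has a replicate check, and all intervals cover counting error only. A peak list was used for each of the 3 readers. The input was not analysed here as a track of its own.

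Per the submitters' processing notes, bcl2fastq 2.17, Trim Galore and HISAT2 were used with the mouse build GRCm38. The peak caller and its version are not given in the sources used here, and the layout is the one MACS2 writes. The deposited lists give, for each peak, a fold (ratio) of the pileup at the summit over the local background. They also give the −log10 of a p-value and a q-value, and a score equal to 10 times the −log10 q as a whole number, by comparison of the deposited columns. The pileup signal at the summit and the peak length in bp are named per the file headers. All of these values are the authors' own, and they serve here only to describe, rank or filter peaks within a list. Peaks were called for each immunoprecipitate separately, with 1 library behind each list. Library totals are not given in the files used here, so sequencing depth is unknown.

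The smallest −log10 q was 2.01 for IGF2BP2, 2.05 for YTHDF2 and 2.02 for YTHDC1. The background behind each peak was computed as (pileup + 1) divided by fold, minus 1, on the assumption that the fold has a pseudocount of 1. Its smallest value in a list, called the floor, was 0.0140 for IGF2BP2, 0.0111 for YTHDF2 and 0.0189 for YTHDC1. At summits that 2 lists had at the same base, the ratio of these backgrounds lay within 1% of the ratio of the floors in 133 of 133 cases for IGF2BP2 and YTHDF2. The same held in 84 of 84 cases for YTHDC1 and YTHDF2 and in 114 of 114 cases for YTHDC1 and IGF2BP2. At these summits the 3 backgrounds were thus those of 1 track apart from a scale factor. The largest pileup was 199, 200 and 200, and the smallest peak width was 100 bp in each list.

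Peaks were assigned with the GENCODE M21 annotation of GRCm38 by the gene under the summit, with exons before introns and protein-coding genes before other types. Regions were taken in the order 3' UTR, 5' UTR, CDS, other exon, intron and intergenic, over all annotated transcripts of the gene. Several equally ranked genes lay under 1.60% of IGF2BP2 summits, 2.08% of YTHDF2 summits and 2.64% of YTHDC1 summits. The lists give no strand, so overlapping and antisense genes are uncertain. Reads shared with paralogs or pseudogenes cannot be traced in a peak list, and 137, 71 and 201 peaks lay in annotated pseudogenes. Repeats and reads that map to several places were not checked at intronic or intergenic peaks.

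Shares have exact binomial 95% intervals. Distance to the stop codon (within 200 nt) and the motif GGAC in 101 bp windows were measured in the longest complete coding transcript of each gene and compared with 1000 draws of positions from the same transcripts. Coinciding peaks (overlap of at least 1 bp) were compared with 1000 random placements in the exons of the same gene, or in the gene body for intronic summits. Shared genes were compared with 1000 draws matched on transcript length in 10 classes, over 21733 protein-coding genes with a complete coding transcript. For 27 gene lists, those with at least 5 members in that set were placed among 10000 random lists of the same size, matched on length. Length is that of the spliced main transcript, so intron length was not matched, although intronic summits count for a gene. Gene expression is not in the files used, so an excess over length-matched genes includes any effect of expression. Unchanged libraries against the shared background were not simulated, because the input track was not used here.

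Gene lists, the planned tests and alternatives, and the rule for named genes were fixed before the data were examined. The tests and alternatives said to be added later were not. The verdict on shared motif sites was lowered to undecided after the result on base composition. Prmt6 and Mfsd2a come first. Per reader the rule then takes the 10 protein-coding genes with the highest fold among peaks with a −log10 q of at least 5, and the 5 with the highest fold among genes bound by that reader alone. It adds the 10 genes bound by all 3 readers whose lowest rank percentile of fold is highest, and 2 to 4 examples by fold for a list. Some lists are given as counts without examples. Genes named outside it are said to be so.

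The alternatives were a −log10 q of at least 5, a fold of at least 5, equal list length (the 2834 peaks with the highest −log10 q), autosomes and X only, and the peak midpoint. Further ones were exonic summits only, any overlap with a gene, overlap of 50% of both peaks, and the genes bound by at least 1 reader as background. Stop codon distances of 100 and 400 nt, windows of 201 and 51 bp, the motif DRACH, and CDS before UTRs completed them. A pileup of at least 5, motif draws within the same part of the transcript, and words of 4 bases with and without CG were added after seeing the data.

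The tests were tested on simulated data. With 2000 uniform summits, observed over expected was 1.00 for the stop codon test and 1.00 for the motif test. With 30% of the 2000 summits moved, it was 2.72 at the stop codon and 1.59 at motif windows. For 2000 peak pairs it was 0.985 at independent places and 5.35 with 30% copied. For gene sets among 21733 genes it was 0.994 when drawn by length and 3.02 with 30% copied. Of 200 random lists of 25 genes among 21733, 4 lay above the 97.5th percentile and 0 below the 2.5th, and 200 of 200 lay above it when 9 bound members were added. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.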

Results

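RNA bound by 3 m6A reader proteins was mapped in primary mouse cells of the lin- c-Kit+ bone marrow fraction, with 1 immunoprecipitate per protein and 1 input. The labels call the cells LIC without spelling it out, and that they are leukaemia cells is taken from the series title. m6A is a methyl mark on adenosines of RNA, and readers are proteins that bind marked transcripts. IGF2BP2 is known as a cytoplasmic protein that stabilises mRNA, YTHDF2 as one that promotes mRNA decay, and YTHDC1 as a nuclear reader. The lists held 7069 peaks for IGF2BP2, 2834 for YTHDF2 and 9963 for YTHDC1. These lay in 2670, 1506 and 4131 protein-coding genes. Sequencing depth is unknown, and no difference between readers has a replicate check. The fold of a peak is the authors' value of pileup over local background.

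The title of the series names a signalling axis of Prmt6, an arginine methyltransferase, and Mfsd2a, a lipid transporter that takes up lysophosphatidylcholine. Prmt6 (ENSMUSG00000049300.11, chromosome 3, 110246109 to 110250998 in GRCm38, minus strand) had 2 peaks in the IGF2BP2 list and 0 in the other lists. Both summits lay in the CDS in exon 1 of 2. The stronger peak, at 110250256 to 110250791, had a pileup of 8, a fold of 7.31 and a −log10 q of 7.54. The weaker one, at 110249892 to 110249991, had a pileup of 4, a fold of 4.02 and a −log10 q of 2.01, and its summit lay 108 nt before the stop codon. Only the stronger Prmt6 peak remained at a −log10 q of at least 5, and 0 remained at equal list length. Of all IGF2BP2 peaks, 53.4% overlapped no peak of either other list, and these had a median pileup of 4. The absence of Prmt6 from the other lists is thus not unusual for peaks this weak.

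Mfsd2a (ENSMUSG00000028655.11, chromosome 4, 122946850 to 122961188, minus strand) had peaks in all 3 lists, most of them in the YTHDF2 list. YTHDF2 had 4 peaks there. The strongest, at 122948834 to 122948949 in the CDS of exon 12 of 14, had a pileup of 10, a fold of 9.22 and a −log10 q of 10.9. The others had folds of 7.21 in exon 3, 5.06 in exon 8 and 7.05 at an intronic summit. The single YTHDC1 peak, at 122948768 to 122948921 in exon 12, overlapped the strongest YTHDF2 peak and had a fold of 5.43 and a −log10 q of 4.04. The single IGF2BP2 peak, at 122949421 to 122949587 in exon 10, had a fold of 5.63 and a −log10 q of 4.54, and lay inside the YTHDF2 peak with the intronic summit (122949193 to 122949617). At a −log10 q of at least 5, 3 YTHDF2 peaks and 0 peaks of the other readers remained, the latter with values of 4.54 and 4.04. At a fold of at least 5, or a pileup of at least 5, all Mfsd2a peaks of the 3 readers remained.

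**Figure D1:**
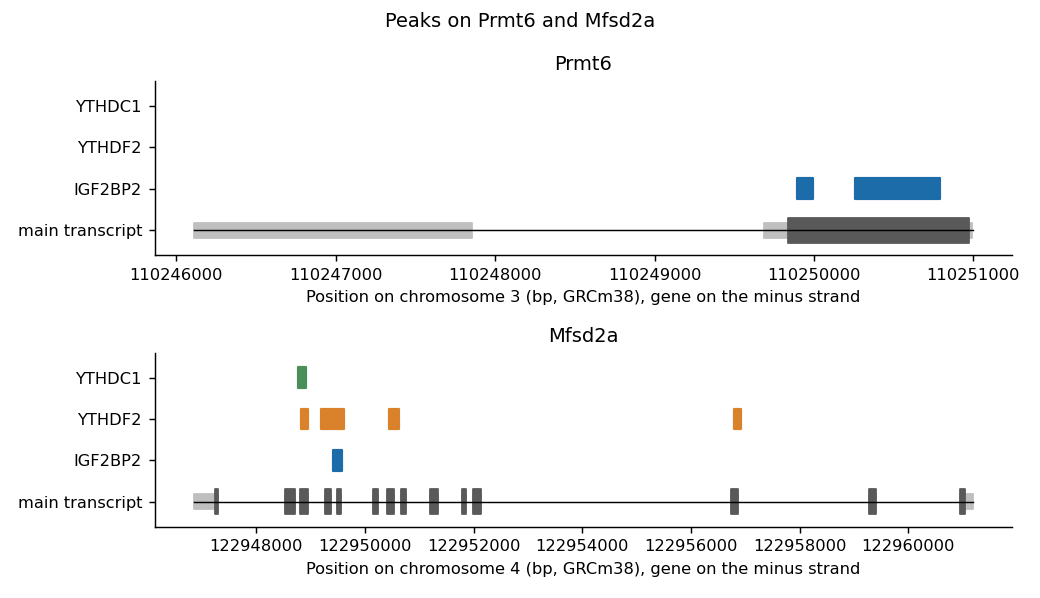
Peaks of the 3 readers (coloured bars) on Prmt6 and Mfsd2a, along chromosome position in bp, with the main coding transcript below (dark blocks, CDS; light blocks, UTR). Prmt6 has 2 IGF2BP2 peaks in its CDS, and Mfsd2a has 4 YTHDF2 peaks beside 1 of each other reader.

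The protein-coding genes with the strongest IGF2BP2 peaks were of varied function, and most of these peaks lay in coding sequence. Dgki, a diacylglycerol kinase, had the highest fold, 79.3, at chromosome 6, 37206726 to 37207653, in an intron. It was followed by an intronic peak in the ETS factor gene Elf1 (72.1, chromosome 14, 79525934 to 79526411). CDS peaks followed in the splicing gene Srrm2 (69.9), the chaperone gene Calr (68.1), the nonmuscle myosin gene Myh9 (67.4), Hsp90aa1 (62.4) and Cdk11b (59.7). An intronic peak in Rnf220 (58.3), a 3' UTR peak in Luc7l2 (57.2) and a CDS peak in Arih1 (56.7) completed the 10. Here and below, a summit was called 3' UTR where any annotated transcript of the gene had one, even if another had CDS there. Over all 7069 peaks the median fold was 5.92 and the median pileup 5.

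Among protein-coding genes, the YTHDF2 list was led by the same Elf1 intron (48.8) and Srrm2 CDS (46.1), and an intergenic peak on chromosome 6 had a fold of 46.2. The ribosomal protein gene Rpl3 followed with a 3' UTR peak of 41.1, then Calr (34.7), an intron of Arhgap21 (34.3), the translation initiation gene Eif3a (32.6), Myh9 (31.5), Hsp90aa1 (30.0), Rnf220 (29.0) and Ythdc1 (28.9). The last of these encodes one of the 3 readers. The median fold was 5.63 and the median pileup 5. In the 10 protein-coding genes with the highest YTHDC1 folds the strongest peak was always intronic, while intergenic peaks reached folds of 73.9 and 65.6. Dock10 led with a fold of 111 at chromosome 1, 80718001 to 80718348. App (76.6), Fras1 (76.4), Pdgfrb (65.3), Nrros (64.8), Arhgap15 (64.1), Tmem241 (63.2), Ptges (61.0), Focad (61.0) and Pfkfb3 (57.9) followed. The median fold was 6.01 and the median pileup 6. Repeats and reads that map to several places were not checked at the intronic and intergenic peaks named here.

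Many peaks rested on few fragments. A pileup of 3 or less stood behind 27.8% of IGF2BP2 peaks, 32.8% of YTHDF2 peaks and 23.4% of YTHDC1 peaks. At a fold of at least 5, 4141, 1538 and 6412 peaks remained, and the order of the 3 lists was the same.

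IGF2BP2 and YTHDF2 peaks lay most often in coding sequence, and YTHDC1 peaks most often in introns. The CDS held 45.7% of IGF2BP2 peaks (exact 95% interval 44.5 to 46.8), 47.1% of YTHDF2 peaks (45.3 to 49.0) and 25.7% of YTHDC1 peaks (24.9 to 26.6). Introns held 25.4% (24.4 to 26.5), 21.4% (19.9 to 23.0) and 37.6% (36.6 to 38.5). The share in 5' UTRs was 3.00%, 4.34% and 7.57%, and that in 3' UTRs 9.68%, 12.3% and 10.0%. With CDS ranked before UTRs, the 3' UTR share was 3.35%, 6.67% and 6.89%.

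**Figure D2:**
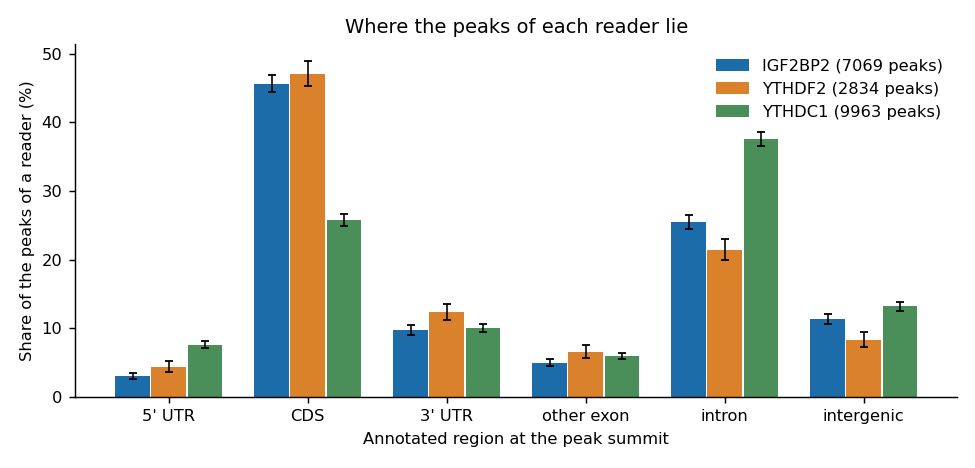
Share of the peaks of each reader (percent, bars) by annotated region at the summit, with exact binomial 95% intervals for counting error as error bars. YTHDC1 has 37.6% of its peaks in introns, against 25.4% for IGF2BP2 and 21.4% for YTHDF2.

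Within main coding transcripts, summits of all 3 readers were fewer in 3' UTRs than in random positions of the same transcripts. The 3' UTR held 5.04% of 4027 IGF2BP2 summits against 29.0% in the draws, 9.32% of 1748 YTHDF2 summits against 29.5%, and 15.2% of 4042 YTHDC1 summits against 32.8%. The CDS held 92.1%, 86.2% and 71.6%, or 1.41, 1.35 and 1.19 times the share in the draws. YTHDC1 summits were in 5' UTRs 1.93 times as often as in the draws, at 13.2%, whereas the ratio was 0.498 for IGF2BP2 and 0.667 for YTHDF2.

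Within 200 nt on either side of stop codons, a region where m6A is known to be dense, the total of summits was not in excess, but the 2 sides differed. Within 200 nt of the stop codon lay 7.45% of IGF2BP2 summits (exact 95% interval 6.66 to 8.30), below all 1000 draws, whose mean was 11.1%. The share was 11.2% for YTHDF2 (9.72 to 12.7) against 12.1% in the draws, and 11.3% for YTHDC1 (10.3 to 12.3) against 12.0%. The latter 2 shares lay inside the central 95% of the draws. In the 200 nt before the stop codon, YTHDF2 had 142 summits against 112 in draws (central 95% 94 to 132) and YTHDC1 293 against 252 (220 to 283), both above the draws, and IGF2BP2 240 against 235. In the 200 nt after it, IGF2BP2 had 60 against 210, YTHDF2 53 against 97.1 and YTHDC1 162 against 233, all below the draws. Summits were also above the draws in bins further into the coding side and below them further into the 3' UTR, so neither sign is particular to the stop codon.

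**Figure D3:**
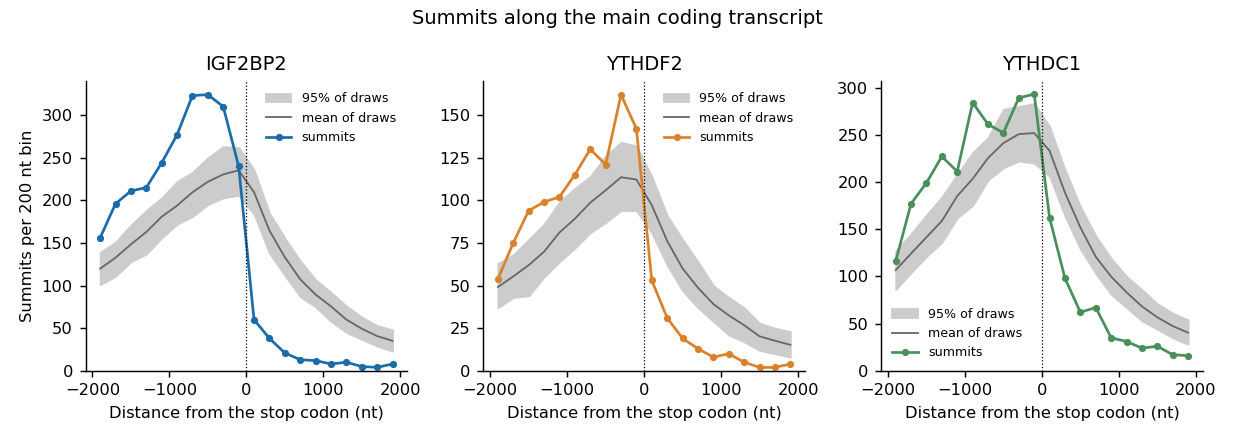
Number of summits per 200 nt bin (coloured points) by distance in nt from the stop codon (dotted line), with the mean (grey line) and central 95% (grey band) of draws from the same transcripts. In each reader summits are above the draws over much of the coding side and below them on the 3' UTR side.

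GGAC, the core of the m6A motif, was more frequent at summits of every reader, whereas the broader motif DRACH was less frequent. A GGAC lay in 42.6% of IGF2BP2 windows (exact 95% interval 41.0 to 44.1) against 35.3% in the draws. For YTHDF2 it lay in 41.8% (39.5 to 44.2) against 35.4%, and for YTHDC1 in 42.4% (40.9 to 43.9) against 36.1%. These shares were above all 1000 draws, with ratios of 1.21, 1.18 and 1.18. DRACH lay in 84.2%, 80.8% and 73.1% of the windows, 0.974, 0.945 and 0.864 times the share in the draws and below all of them.

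Peaks of different readers fell on the same places more often than their genes alone would give. Of the 2834 YTHDF2 peaks, 1859 (65.6%) overlapped an IGF2BP2 peak and 1626 (57.4%) a YTHDC1 peak. Of the 7069 IGF2BP2 peaks, 2723 (38.5%) overlapped a YTHDC1 peak. Inside genes, 1737 YTHDF2 peaks coincided with IGF2BP2 peaks where random placement gave 306 (ratio 5.67). For IGF2BP2 and YTHDC1 the numbers were 2388 and 470 (ratio 5.08), and for YTHDF2 and YTHDC1 1519 and 267 (ratio 5.69). None of the 1000 placements gave as many in any pair. Places were drawn evenly over the exons or gene body. The excess thus includes any effect of a preference for coding sequence that the lists share. The 3 lists appear to share 1 background track, so part of the excess may come from the shared control.

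**Figure D4:**
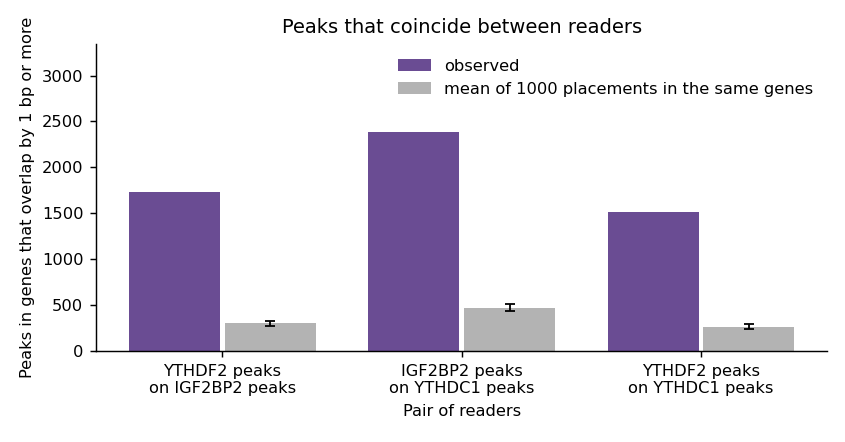
Peaks in genes that overlap a peak of the other reader (purple bars, number of peaks) and the mean of 1000 random placements in the same genes (grey bars, with the central 95% of placements) for the 3 pairs. Observed numbers are 1737, 2388 and 1519, against 306, 470 and 267.

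The places with the highest ranks in all 3 lists were an intron of Rnf220 (a ubiquitin ligase gene; chromosome 4, 117424674 to 117425099 in the IGF2BP2 list) and coding sequence of Calr (chromosome 8, 84842637 to 84842958) and Hsp90aa1 (chromosome 12, 110694045 to 110694753). Their folds in the order IGF2BP2, YTHDF2 and YTHDC1 were 58.3, 29.0 and 52.9 for Rnf220, 68.1, 34.7 and 46.1 for Calr, and 62.4, 30.0 and 45.9 for Hsp90aa1. Rpl3, Hmgb1, Nrros, Cdk11b, Srrm2, Cdk6 and Ythdc1 completed the 10. The Ythdc1 peaks lay in its CDS, with folds of 45.1, 28.9 and 37.6. A total of 1249 IGF2BP2, 1257 YTHDF2 and 1246 YTHDC1 peaks overlapped both other lists, with median folds of 10.8, 7.29 and 9.71. Peaks without any partner made up 53.4%, 21.4% and 68.9% of the lists, with median folds of 4.93, 3.96 and 5.86.

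Most genes in the YTHDF2 list were also in another list, and YTHDC1 had the most genes of its own. Of 4974 protein-coding genes with any peak, 1049 were in all 3 lists, 1967 in that of YTHDC1 alone, 593 in that of IGF2BP2 alone and 130 in that of YTHDF2 alone. The genes with the highest folds among those bound by YTHDC1 alone were Ldlrad4 (45.8), Pid1 (38.4), Commd10 (36.7), Prkcb (33.9) and Slc38a8 (28.6), all intronic. For IGF2BP2 alone they were Phactr3 (23.2), Gm10778 (21.7), Ankhd1 (20.5), Stk39 (18.7) and Wnt2 (17.8), intronic too except Ankhd1 (CDS). For YTHDF2 alone they were C130060K24Rik (8.38), Cadm2 (7.63), Glcci1 (7.29), Nova2 (7.29) and Kcnc2 (7.29), intronic except Glcci1 (CDS) and Nova2 (5' UTR). Repeats were not checked at these intronic places.

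Among 21733 genes, 1047 were shared by all 3 lists, against 65.7 in draws matched on length and 34.8 for independent lists. IGF2BP2 and YTHDF2 shared 1163 (238 in the draws, 183 if independent), IGF2BP2 and YTHDC1 1954 (642 and 505), and YTHDF2 and YTHDC1 1254 (357 and 284). All were above the 1000 draws. With only the 4959 tested genes bound by at least 1 reader as background, the ratio to the draws was 1.43 for IGF2BP2 and YTHDF2, 0.881 for IGF2BP2 and YTHDC1, 1.01 for YTHDF2 and YTHDC1, and 1.55 for all 3.

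Genes of RNA handling and protein synthesis were widely bound, as were those of other lists given below, such as glycolysis. Of 23 hnRNP genes, which encode nuclear RNA-binding proteins, 21 had an IGF2BP2 peak, 16 a YTHDF2 peak and 20 a YTHDC1 peak, against 3.30, 1.87 and 5.01 in random lists. Examples from the IGF2BP2 list were Hnrnpu (fold 34.6) and Hnrnpc (33.4). Of 21 translation factors, 18, 18 and 19 had peaks, with Eif3a at folds of 56.0, 32.6 and 34.8 and Pabpc1 at 43.2, 25.2 and 29.6. Of 18 chaperone and endoplasmic reticulum stress genes, 16, 13 and 16 had peaks, of 18 SR splicing genes 13, 9 and 14, and of 83 ribosomal protein genes 35, 29 and 41. Of 32 chromatin regulators, 25, 17 and 28 had peaks, with Smarca4 at a fold of 49.0 for IGF2BP2 and Arid1b at 39.1 for YTHDC1. Each of these counts lay above the 97.5th percentile of 10000 random lists, which were not matched on expression. With only bound genes as background, the IGF2BP2 and YTHDF2 counts still did, whereas none of the 6 YTHDC1 counts did: they lay at percentile 69.9 for hnRNP genes, 92.8 for translation factors, 88.0 for chaperones, 96.8 for SR genes, 28.2 for ribosomal proteins and 95.5 for chromatin regulators.

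Transcription factors of stem and leukaemia cells had a peak most often in the YTHDC1 list, which is also the longest. Of 36 such genes, 28 had a YTHDC1 peak (9.01 in random lists), 14 an IGF2BP2 peak (6.07) and 9 a YTHDF2 peak (3.33), and 12 had a YTHDC1 peak alone. Myb, a regulator of blood progenitors, had folds of 46.9 for IGF2BP2, 28.5 for YTHDF2 and 22.7 for YTHDC1. Zeb2 had folds of 13.4, 5.93 and 23.6 in the same order. Among bound genes alone, the YTHDC1 count of this list stayed at the 99.8th percentile, whereas the IGF2BP2 count was at percentile 31.9. The random lists are matched on spliced transcript length and not on intron length, and introns held 37.6% of YTHDC1 peaks. An effect of intron length on the YTHDC1 count was thus not separated. Of 33 surface and signalling genes 10, 7 and 18 had peaks (IGF2BP2, YTHDF2 and YTHDC1), with Stat3 at folds of 17.0, 6.38 and 5.89 and Cd47 at 13.4, 8.65 and 15.7. Of 26 genes described as m6A targets in acute myeloid leukaemia, 9, 9 and 13 had peaks. That list contains Prmt6, so it is not independent of the study. Of 14 genes of m6A writers and erasers 4, 2 and 8 had peaks, with Virma at folds of 18.7, 7.91 and 15.5 and Zc3h13 at 7.16, 6.71 and 15.5. Of 14 reader genes 7, 5 and 6 had peaks. Of 10 arginine methyltransferases 3, 1 and 1 had peaks, and of 16 genes of choline and lysophosphatidylcholine handling 3, 3 and 6.

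Of 17 lymphoid markers 0 had a peak of any reader, against 1.98, 1.11 and 3.08 in random lists for IGF2BP2, YTHDF2 and YTHDC1, and only the YTHDC1 count lay below the 2.5th percentile. Of 13 erythroid markers only Tfrc had a peak (YTHDC1, fold 5.27), of 9 megakaryocyte markers only Itga2b, and of 12 stromal and endothelial markers only Pecam1 and Col1a2 (both YTHDC1). The counts of these 3 lists lay within the central 95% of random lists. Of 26 myeloid differentiation genes 3, 2 and 7 had peaks, against 1.89, 1.13 and 3.13, and the YTHDC1 count, led by Irf8 (fold 14.6) and Prtn3 (11.5), lay at percentile 98.4 (65.7 among bound genes). Of 421 zinc finger genes 33, 14 and 65 had peaks, below the 2.5th percentile for each reader (64.4, 35.5 and 96.4 in random lists). Among bound genes the YTHDC1 count turned direction, to percentile 74.8. Of 19 glycolysis genes 11, 6 and 13 had peaks, and of 32 genes of DNA replication and mitosis 14, 6 and 15. Of 98 histone genes 11, 10 and 18 had peaks. These counts all lay above the 97.5th percentile. Of 21 apoptosis genes 5, 6 and 11 had peaks, and of 21 nuclear genes of oxidative phosphorylation 3, 7 and 8, above it for YTHDF2 and YTHDC1 only. Of 10 mitochondrial genome genes 0, 0 and 1 had peaks, within the central 95%. Of 25 lists tested, 13, 15 and 16 lay above the 97.5th percentile for IGF2BP2, YTHDF2 and YTHDC1. With bound genes as background, 7, 7 and 1 did (8 for YTHDF2 in a second set of random lists). That background is made of the 3 lists themselves, and YTHDC1 holds 4131 of the 4974 genes, so it leaves little room for an excess.

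**Figure D5:**
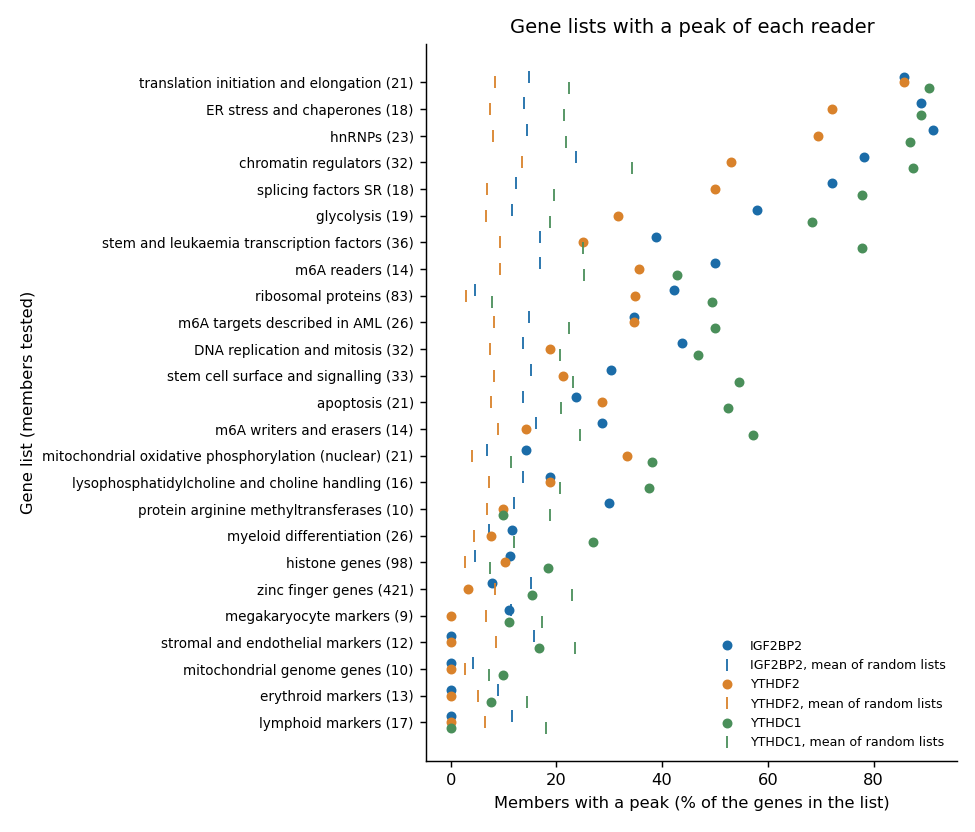
Share of the members of 25 gene lists with a peak of each reader (points, percent of the members tested, number in brackets) and the mean of random lists matched on transcript length (ticks). Translation factors, chaperones and hnRNP genes lie far above their ticks, and 0 of 17 lymphoid markers have a peak.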

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

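The tests in this part were written down before their results were seen. Exceptions in timing are the test of base composition, added once the overall excess of GGAC was known, and the depth test on pileups under 15, added once that on higher pileups had been run. The verdict on shared motif sites was lowered to undecided after the composition result. Peaks outside any annotated gene entered the list totals, the region shares and the overlap shares above, but none of the comparisons of genes or transcripts. They numbered 801 for IGF2BP2, 235 for YTHDF2 and 1315 for YTHDC1, and are listed for that reason alone, since no level in a control was there to compare them with. Of each list, 80 overlapped both other lists. The strongest was a YTHDC1 peak at chromosome 2, 79216059 to 79216276, with a fold of 73.9 and a pileup of 85, which coincided with peaks of both other readers. The strongest IGF2BP2 one lay at chromosome 8, 31420215 to 31420626, with a fold of 52.9.

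The YTHDF2 list was the shortest, and a shallower library is a candidate explanation. The ratio of the background floors, 1.26 for IGF2BP2 against YTHDF2, was used in place of the unknown relative depth. It rests on the assumed pseudocount. Of 83 IGF2BP2 peaks at the floor with a pileup of at least 15, 24 had no YTHDF2 peak, where lower depth with counting error alone predicted 0.0126, or 2.08 with a further halving of the signal, so depth alone does not account for these, although variation between separate immunoprecipitates was not modelled and could. Of 2455 with a pileup under 15, 2077 had none, where depth predicted 1007, or 1824 with the halving. The limit set for this part, 3647, exceeded the number of peaks, so that test could not have excluded depth, and both depth and an untested difference between the proteins stay open.

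Peaks of different readers coincided, which positions with little input coverage could produce through the shared background, as could RNA that adheres to any immunoprecipitate (not tested, since no control antibody was analysed here). Among peaks with a background of at least 10 times the floor, the ratio of observed to expected coincidence was still 4.56 in the lowest of the 3 pairs, above every placement. The coincidence was thus not confined to peaks at the floor. The floors were only 0.0111 to 0.0189, however, and this background was computed from the fold and not read from the input at the summit. The test could therefore not exclude low input coverage. Ratios at the floor were higher (7.86 for YTHDF2 and IGF2BP2, 6.21 for IGF2BP2 and YTHDC1, 7.86 for YTHDF2 and YTHDC1). The shares of peaks that coincided went the other way. In the same order they were 57.1%, 23.6% and 39.6% at the floor, and 79.2%, 79.5% and 84.7% at 10 times the floor or more. A contribution of low input coverage stays open. Shared m6A motif sites are a biological alternative: GGAC was above all draws in peaks common to the 3 lists, with a lowest ratio of 1.19. Over all windows, however, other words of the same letters were as enriched, most of them with CG. Words were not counted in the common peaks alone, so this test could not decide. For GGAC, peaks found in 1 list alone were above all draws too for IGF2BP2 (1.21) and YTHDC1 (1.16), but not for YTHDF2 (1.08, 152 of 1000 draws as high).

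YTHDC1 peaks were more often intronic, and a longer list with weaker peaks could bring this about. At equal list length the YTHDC1 intron share was 33.3% (exact 95% interval 31.6 to 35.1), still above the 22.6% of IGF2BP2 (21.1 to 24.2), which argues against list length as the whole cause. The nuclear location known for YTHDC1 remains a hypothesis, since 1 library per protein cannot separate it from a difference between preparations.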

How the results depend on the processing

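With 1 library per reader, the alternatives test the processing and not the biology, and depth is unknown. A pileup of at least 5, motif draws within the same part of the transcript and the split of words by CG were chosen after seeing the data, and the other settings before. Excess coincidence of peaks kept its direction and its side of the draws under all alternatives run, with ratios from 5.09 to 11.2. The deficit of IGF2BP2 summits within the stop codon window did too, at 0.553 to 0.771. It lies in the 200 nt after the stop codon (60 against 210) and not in those before it (240 against 235), and is part of the 3' UTR deficit. Except where a cause is named, the cause was not tested.

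DRACH in place of GGAC turned the motif ratio to 0.974 (IGF2BP2), 0.945 (YTHDF2) and 0.864 (YTHDC1). With draws from the same part of the transcript it was 0.963, 0.940 and 0.889, and GGAC gave 1.10, 1.08 and 1.08. Near the stop codon, the YTHDF2 ratio fell below the draws at a −log10 q of at least 5 (0.852), and that of YTHDC1 within 400 nt (0.908).

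With bound genes as background, which removes genes in none of the lists and so lowers the ratios of pairs by construction, the ratio of shared genes was 0.881 for IGF2BP2 and YTHDC1 and 1.01 for YTHDF2 and YTHDC1, and 7, 7 and 1 lists lay above the 97.5th percentile (8 for YTHDF2 in a second set of random lists). Percentiles crossed the middle for IGF2BP2 in stem and leukaemia transcription factors (31.9), surface and signalling genes (27.5) and leukaemia m6A targets (47.0). For YTHDC1 they crossed it in leukaemia m6A targets (26.7), oxidative phosphorylation (40.9), ribosomal proteins (28.1), histones (35.7) and zinc finger genes (74.0).

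Stricter lists held fewer peaks by construction. At a fold of at least 5, 4141 IGF2BP2, 1538 YTHDF2 and 6412 YTHDC1 peaks remained, with 1670 IGF2BP2 and 837 YTHDF2 genes. Intron shares were then 23.6%, 18.6% and 36.2%, CDS shares 47.7% (IGF2BP2) and 27.3% (YTHDC1), and 3' UTR shares 8.33% and 9.37%. A pileup of at least 5 left 4207, 1572 and 6557 peaks and 1687 and 848 genes, with intron shares of 23.6%, 18.7% and 36.1%, CDS shares of 47.4% and 27.1%, and 3' UTR shares of 8.30% and 9.29%. A −log10 q of at least 5 gave 8.75% of IGF2BP2 peaks in 3' UTRs, and for YTHDC1 27.0% in CDS and 36.3% in introns.

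Equal list length left 1249 IGF2BP2 and 1627 YTHDC1 genes. Intron shares were 22.6% and 33.3%, CDS shares 49.9% and 30.8%, and 3' UTR shares 8.19% and 9.03%, and 10 lists lay above the 97.5th percentile for YTHDC1. The peak midpoint gave 23.2% of YTHDF2 peaks in introns, and for YTHDC1 38.8% in introns and 24.8% in CDS. CDS before UTRs gave 52.8%, 53.6% and 29.3% in CDS and 3.35%, 6.67% and 6.89% in 3' UTRs, by construction of the order.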

Other observations

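All values in this part were looked for after the results above had been seen. Intronic YTHDC1 peaks lay near gene starts more often than random places in the same genes. Of 3537 intronic YTHDC1 peaks in coding genes, 12.7% (exact 95% interval 11.6 to 13.8) lay within 2000 nt of the start of the gene, against 5.11% in 1000 draws, none of which was as high. The share was 4.51% for IGF2BP2 (5.50% in the draws) and 6.07% for YTHDF2 (7.22%). Some noncoding RNAs also had peaks. Of 18 nuclear and long noncoding RNAs in a gene list, 5 had an IGF2BP2 peak, 5 a YTHDF2 peak and 6 a YTHDC1 peak. Malat1, a nuclear RNA, had peaks in all 3 lists, with folds of 26.2 for IGF2BP2, 29.1 for YTHDF2 and 25.3 for YTHDC1. Neat1, another nuclear RNA, had 2, 3 and 10 peaks with top folds of 8.66, 12.0 and 23.7. Annotated snoRNA and snRNA genes held 1, 4 and 27 peaks.

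The genes with the most peaks, named after their values were seen, were Syne1 (38 peaks) for IGF2BP2, Myh9 (19) for YTHDF2 and Rnf220 (34) for YTHDC1. Myh9 also had 24 IGF2BP2 and 22 YTHDC1 peaks. The main transcripts of Syne1, Myh9 and Rnf220 are 27908, 7433 and 3029 nt long without introns. The strongest Rnf220 peak was intronic, so its count of peaks is not a density along the spliced transcript. The widest peak of each list was 5813, 5825 and 5857 bp long and lay in Gm26917 on chromosome 17, with pileups of 195, 197 and 200. The largest pileups in the lists were 199, 200 and 200. Gm26917 is annotated as a lincRNA, but the place was looked at here as the ribosomal RNA locus. Binding of a long noncoding RNA should not be read from it.

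The excess of GGAC at summits may reflect base composition rather than the motif itself. If so, other words with the same letters would be enriched as well, and at least 7 of the 11 other arrangements of the letters of GGAC were as enriched as GGAC in every reader, which meets the rule set for base composition. Yet 6 of them contain CG, and of the 5 without CG only 1 (IGF2BP2), 1 (YTHDF2) and 2 (YTHDC1) were as enriched, with the same numbers in draws from the same part of the transcript. The test thus does not separate base composition from a preference of summits for CG. GGAC ranked 50th of 256 words of 4 bases for IGF2BP2, 59th for YTHDF2 and 58th for YTHDC1. The most enriched words were GACG (1.68 for IGF2BP2, 1.72 for YTHDF2) and CGCG (2.14 for YTHDC1), and 7, 7 and 10 of the 10 most enriched contain CG. These ranks are against draws from the whole transcript. Against draws from the same part, 5, 4 and 6 of the 10 most enriched contain CG. The median ratio of words with CG was then 1.12, 1.12 and 1.11, against 1.27, 1.26 and 1.38 for the whole transcript. Purines made up 61.1%, 59.9% and 59.2% of the windows, against 55.1%, 54.5% and 53.1% in draws from the same part of the same transcripts. A role of m6A at these sites was not measured here, since the lists hold no methylation data.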
